A study of Mus musculus with 8 samples.

How the data were processed

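RNA from sorted multipotent progenitors of 4 Elektra and 4 wild-type samples was hybridised to Affymetrix mouse arrays, 1 array per sample. Per the labels, marrow of 2 mice of 1 genotype was pooled in each sample, and the series description speaks of 4 mice per genotype. The number of animals behind each group is therefore not settled here. Cells were enriched for c-Kit, sorted by flow cytometry with dead cells excluded, and frozen in lysis buffer, per the labels' protocols. Between 100 and 200 pg of total RNA was amplified with 12 cycles of PCR before in vitro transcription, per the labels' protocols. The authors' deposited log2 values were made with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. Those steps correct the background, normalise between arrays and summarise probes, and are meant to put all arrays on 1 scale. Elektra replicate 2 still had a narrower spread of values than the other arrays. The genome build behind the annotation is not given in the sources used here, and no coordinates are printed.

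The deposited series table held log2 values of 41345 probe sets in the 8 arrays. A deposited annotated table held log2 values of 34390 of these with gene symbols, and the authors' fold changes and p-values for Elektra against wild type. The authors' deposited p-values equalled those of a pooled-variance test on their log2 values to within 2.88e-12. The log2 values of the 2 tables differed by at most 0.291, with a median difference of 0.0607. The series table was used throughout and the annotated table supplied the symbols. Of its probe sets, 31872 had 1 symbol, 1 had several and 2517 had none. The 6955 probe sets outside the annotated table were not tested by gene. Older symbols in the gene lists were matched through the synonyms of the RefSeq table of assembly GRCm38.p6, used for names alone. All arrays were distinct, the highest correlation of any pair over the 41345 probe sets being 0.979.

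Each gene was represented by the probe set with the highest mean over all 8 arrays, giving 30918 genes, with no filter on dim probe sets. Of the 659 genes with several probe sets, 1 had probe sets that passed an unadjusted p of 0.05 in opposite directions. Elektra was compared with wild type by lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Before the data were examined, 31 gene lists were fixed. Of these, 3 (the Schlafen family, the sort markers and sex-linked genes) are given gene by gene. The other 28 were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 28 lists. Alongside them ran camera with an estimated correlation, fry, and exact permutation tests over the 70 relabelings of a list's mean level per array. With 4 arrays against 4 the smallest p such a test can give is 0.0286.

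The genes named were set by rule before the data were examined. They are the Schlafen family, the sort markers, up to 12 genes per direction, and up to 4 members with the smallest p of each list described. The 12 per direction were to pass the threshold with separate groups. As none did, they were filled by the smallest unadjusted p among genes with p under 0.01, separate groups and a log2 change of at least 0.5, passing over 28 predicted genes and RNAs without a function name. Members are named for the lists with an adjusted p under 0.10 and for those on the cell cycle, quiescence, lymphoid priming, interferon and immediate-early genes. This choice of lists was made after the values were seen; members had first been named for all 28. Of the genes this rule names, 2 are not reported here and were not replaced, nor is 1 of the B cell genes looked at singly. The whole procedure was tested on simulated data with 200 genes above the median level changed by known amounts, over 10 runs, each gene keeping its own spread. It recovered 16.4%, 68%, 87.2% and 94.6% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale. Calls outside the 200 genes numbered 6.3 per run on average. These include any among the long-term HSC genes, which were shifted in the same runs, so not all need be false. A shift of -0.3 in the long-term HSC list was found in 100% of runs. The simulated noise was drawn for each gene on its own, so these runs held no inter-gene correlation. In the real arrays that list had an estimated correlation of 0.114 and a smaller median shift of -0.12. The simulation therefore does not show how reliable a list call is on the real arrays.

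Alternatives fixed beforehand were quantile normalisation, median centring, a filter on dim probe sets at the 40th percentile, the mean of a gene's probe sets, all annotated probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, the annotated table as input, leaving out each array, an adjusted p of 0.10, limma's treat against a fold of 1.2, and the other list tests. Control probe sets are not marked in the tables used here, so the alternative with all probe sets used those of the annotated table; all 41345 of the series table were fitted besides. After the data were seen, a batch term for arrays numbered 1 and 2 against 3 and 4, fits without 2 or 3 arrays that stand apart, and the pooled-variance test were added. The labels name no batch. The labels call the samples biological replicates. Whether pools of 1 genotype shared animals is not settled by them, since the number of mice is not. The SDs and tests given here take the samples as independent.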

Results

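Gene expression was measured in multipotent progenitors, a population below the long-term haematopoietic stem cell (HSC), sorted from the bone marrow of untreated mice. The 4 Elektra arrays came from mice homozygous for a loss-of-function allele of Slfn2, a member of the Schlafen family known for its part in keeping immune cells quiescent. The 4 wild-type arrays came from littermates. Cells were sorted as Lin- Sca-1+ c-Kit+ (LSK) CD48- CD150-, and marrow from 2 mice was pooled for each sample. The comparison asks how loss of Slfn2 alters the steady-state transcriptome of these progenitors. Expression is given as log2 intensity. The array medians lay between 2.02 and 2.06, and any pair of arrays correlated at 0.942 or higher across probe sets. Elektra replicate 2 stood apart on the whole profile, with an upper quartile of 3.57 against 3.76 to 3.85 in the other arrays, a lower quartile of 1.36 against 1.28 to 1.30, and a first principal component (28.8% of the variance) of -47.8 against -0.271 to 14.5. Xist stayed near the bottom of the range in both genotypes (1.05 ± 0.16 in Elektra and 1.15 ± 0.08 in wild type, SD, n = 4). The Y-linked Ddx3y was 5.32 ± 0.32 and 5.43 ± 0.26.

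The 2 genotypes had closely similar profiles. Of 30918 genes, 0 passed an adjusted p of 0.05 in limma, with 0 higher and 0 lower in Elektra, and the lowest adjusted p was 0.885. At an unadjusted p under 0.05 there were 1690 genes, 800 higher and 890 lower, where 1545.9 were expected by chance. The 4 Elektra values lay wholly to one side of the 4 wild-type values for 1001 genes, or 3.24%, against the 2.86% that chance gives. The 95% confidence interval of the log2 change lay inside -1 to 1 for 97.5% of all genes and for 95.6% of those above the median level. Among genes above the median level the SE of the log2 change had a median of 0.146. The pooled-variance test gave 0 genes after adjustment as well, with 1560 at an unadjusted p under 0.05. In simulated data of the same size, with changes given to genes above the median level, 68% of those changed by 1 on the log2 scale and 16.4% of those changed by 0.5 were recovered.

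Slfn2 itself was measured at the same level in both genotypes. Its log2 intensity was 2.01 ± 0.08 in Elektra and 2.00 ± 0.30 in wild type (SD, n = 4), a difference of 0.01 with a 95% interval from -0.31 to 0.33 (limma adjusted p = 0.994). The signal was weak, at the 49.5th percentile of all genes. The Elektra allele is known as a coding change, so the transcript level does not check the genotype labels. The other 8 measured Schlafen genes did not pass either, over all genes or adjusted over the list alone. Slfn14 was 1.86 ± 0.15 in Elektra and 1.63 ± 0.10 in wild type, and Slfn8 was 4.16 ± 0.68 and 4.11 ± 0.44. Slfn1 (0.06), Slfn3 (-0.07), Slfn4 (0.09), Slfn5 (-0.07), Slfn9 (-0.17) and Slfn10-ps (-0.08) differed by less than 0.20 in log2 change. The sign turned for all of these but Slfn4, and for Slfn8 and Slfn2, on leaving out 1 array or another (Slfn2 -0.12 without wild type replicate 2).

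None of the 6 genes of the sort marker list passed between genotypes, over all genes or adjusted over the list alone. Kit, the stem cell factor receptor, was 8.96 ± 0.12 in Elektra and 9.16 ± 0.09 in wild type, and Ly6a, which encodes Sca-1, was 9.27 ± 0.16 and 8.90 ± 0.36. Of the genes of the 2 surface proteins excluded by the gate, Cd48 was 3.92 ± 0.16 and 3.76 ± 0.36, and Slamf1, which encodes CD150, was 1.75 ± 0.34 and 1.60 ± 0.34. Levels of different genes come from different probes and are not compared. Cd34 and Flt3 are on the same list without being part of the gate. Cd34 was 8.40 ± 0.06 and 8.42 ± 0.18. Flt3, the cytokine receptor that marks lymphoid-primed progenitors, was 7.08 ± 0.16 in Elektra and 7.42 ± 0.07 in wild type, with no overlap between the arrays. Its log2 change of -0.34 (SE 0.10) had a limma adjusted p of 0.885 over all genes and of 0.0505 adjusted over the list alone.

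**Figure D1:**
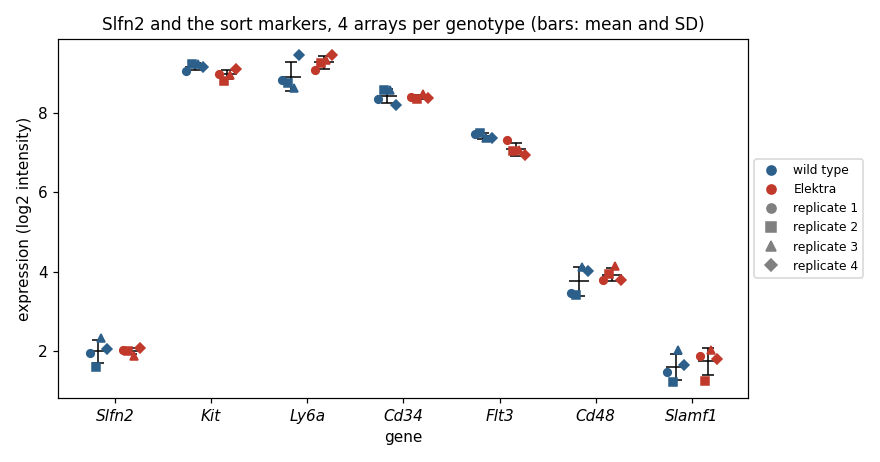
Log2 intensity (vertical axis) of Slfn2 and the 6 genes of the sort marker list in each array, with the mean and SD of each genotype. Of these genes only Flt3 has no overlap between Elektra (mean 7.08) and wild type (mean 7.42).

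No single gene passed, so the genes leading each direction are those with an unadjusted p under 0.01, separate groups and a log2 change of at least 0.5. There were 95 of them, 23 higher and 72 lower in Elektra. At an unadjusted p under 0.01, without the other conditions, there were 305 genes, where 309.18 were expected by chance. The 95 were not counted again under the alternatives, so the firmness of their lean was not tested. At an unadjusted p under 0.05, 800 of 1690 genes were higher in the main fit, and the alternatives went both ways. With quantile normalization 1209 of 1826 were higher, and without Elektra replicate 2, 876 of 1575. With dim probe sets left out 409 of 1062 were higher, and without wild type replicate 1, 600 of 1408. The smallest unadjusted limma p, 5.37e-05, belonged to Zufsp (now Zup1), a deubiquitinase active in the response to DNA damage, at 5.45 ± 0.12 in Elektra and 6.18 ± 0.15 in wild type. Gga3, an adaptor for sorting at the trans-Golgi network, was 4.09 ± 0.14 and 4.79 ± 0.18. The cytokine gene Clcf1 was 3.92 ± 0.05 and 4.45 ± 0.12, and the zinc finger gene Zfp948 had the widest gap of the 24 named, -1.13 (SE 0.22). The other named genes with lower values were Mir669f (-0.71), Mir568 (-0.71), Elac1 (-0.69), Mirlet7a-2 (-0.68), Dynlt1f (-0.63), Gripap1 (-0.55), D2hgdh (-0.53) and Phxr4 (-0.95) in log2 change. On the other side, the antiviral gene Rsad2 was 3.93 ± 0.18 in Elektra and 3.40 ± 0.07 in wild type. Mapk11, which encodes a p38 kinase, was 4.21 ± 0.39 and 3.43 ± 0.04, and Bace1, the beta-secretase gene, was 3.32 ± 0.20 and 2.62 ± 0.26. The adenosine receptor gene Adora2b (0.57), the epoxide hydrolase gene Ephx1 (0.52), Mir674 (0.70), Olfr279 (0.59), H2-M1 (0.53), Phf11d (0.53), Apof (0.52), Vmn1r175 (0.55) and Ighv2-1 (0.51) followed in log2 change. Ighv2-1, H2-M1, Apof and Vmn1r175 were dim, between the 31.7 and 40.2 percentiles of all genes. All 24 had a limma adjusted p of 0.885.

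Genes of long-term HSCs were lower as a group in Elektra progenitors. Of the 30 measured, 23 were lower and 7 higher, the median log2 change was -0.12, and the list fell in limma's camera test (adjusted p = 0.0246). The call was lost with the inter-gene correlation estimated (adjusted p = 0.980 with an estimated correlation). Meis1, a transcription factor gene of stem cell self-renewal, was 8.25 ± 0.15 in Elektra and 8.52 ± 0.07 in wild type, and Trpc6 was 4.22 ± 0.17 and 4.76 ± 0.31. Ly6a, also on this list, lay the other way. None of the 30 passed alone, over all genes or adjusted over the list alone. The median change was -0.08 between arrays numbered 1 and 2 and -0.14 between those numbered 3 and 4. The list did not pass without Elektra replicate 3 (median -0.0416, adjusted p = 0.227), without wild type replicate 1 (-0.0705, 0.223), with quantile normalization (-0.0582, 0.0685) or without the 2 arrays with immunoglobulin signal (-0.0719, 0.283). The median turned to 0.00872 (adjusted p = 0.826) without the 3 arrays that stand apart (Elektra replicates 2 and 3 and wild type replicate 4), and over all alternatives run the adjusted p lay between 0.00138 and 0.989. An exact permutation test of its mean level, 4.78 ± 0.11 against 4.88 ± 0.08, gave p = 0.171.

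The other list to pass held mast cell, basophil and eosinophil genes, and its signal was close to the floor of the arrays. Of 15 measured genes 12 were higher in Elektra, with a median log2 change of 0.12 (camera adjusted p = 0.0458; adjusted p = 0.677 with an estimated correlation). Its mean level was 1.53 ± 0.06 in Elektra and 1.44 ± 0.06 in wild type. The mast cell protease genes Mcpt4 (0.99 ± 0.12 and 0.79 ± 0.06) and Cma1 (1.16 ± 0.24 and 0.93 ± 0.06) lay at the 5.52 and 12.1 percentiles of all genes. Prss34 (1.55 ± 0.07 and 1.38 ± 0.16) and Tpsb2 (1.61 ± 0.12 and 1.45 ± 0.18) lay at the 31.0 and 33.7 percentiles. Dim genes in general leaned the same way. Below the median level, 393 genes were higher and 155 lower at an unadjusted p under 0.05, while above it 407 were higher and 735 lower. Without Elektra replicate 2 these counts were 289 and 207 below and 587 and 492 above, and with quantile normalization 349 and 194 below and 860 and 423 above, which turns the lean above the median. Leaving out Elektra replicate 2 (adjusted p = 0.0963), Elektra replicate 3 (0.0639), wild type replicate 2 (0.0529), wild type replicate 3 (0.101) or wild type replicate 4 (0.0675) ended the call, as did quantile normalization (0.108) and leaving out the 2 arrays with immunoglobulin signal (0.283) or the 3 that stand apart (0.826), and over all alternatives run the adjusted p lay between 0.0173 and 0.826.

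Cell cycle and quiescence genes, on which Slfn2 is known to bear, did not pass as groups. Of 34 G2/M and mitosis genes 26 were higher in Elektra, with a median of 0.12 and a camera adjusted p of 0.0674 (0.980 with an estimated correlation). Ccna2 (4.76 ± 0.37 and 4.35 ± 0.15), Ccnb2 (5.37 ± 0.38 and 4.97 ± 0.27), Aurka (2.98 ± 0.25 and 2.72 ± 0.11) and Nuf2 (3.23 ± 0.46 and 2.70 ± 0.60) had the smallest p-values. The median was -0.02 between arrays numbered 1 and 2 and 0.22 between those numbered 3 and 4. It was 0.0124 without Elektra replicate 4 (adjusted p = 0.956), 0.0605 without wild type replicate 1 (0.419) and 0.23 without the 3 arrays that stand apart (1.26e-06). That last fit set 2 Elektra arrays against 3 wild-type ones. Its p rests on the preset inter-gene correlation of 0.01, where the estimate over all arrays was 0.358. Of the 8 fits that left out 1 array, 5 passed. With quantile normalization the median was 0.18 (adjusted p = 0.00429). The adjusted p over all alternatives run lay between 1.26e-06 and 0.989. The G1/S and DNA replication genes went both ways, with 14 of 35 higher (median -0.05, adjusted p = 0.617). They passed in opposite directions without Elektra replicate 2 (median 0.13, adjusted p = 0.00531) and without Elektra replicate 3 (median -0.14, adjusted p = 0.0482). These genes also differed between arrays numbered 1 and 2 and those numbered 3 and 4 (median -0.44), and both fits are unequal in that split. The difference was -0.55 in Elektra and -0.14 in wild type. Elektra replicate 2 had the lowest mean level of the list, 4.01, against 4.39 (wild type replicate 1) to 4.83 (Elektra replicate 3) in the other arrays. The replication licensing gene Cdc6 was 4.18 ± 0.35 in Elektra and 3.67 ± 0.10 in wild type, and Ccne1 was 3.62 ± 0.35 and 3.20 ± 0.34, whereas Fen1 (-0.33) and Gins3 (-0.32) had negative log2 changes. Of 27 quiescence genes and CDK inhibitors 16 were lower (median -0.04, adjusted p = 0.256), with a pass without Elektra replicate 1 (median -0.16, adjusted p = 0.0291) or wild type replicate 4 (median -0.0849, adjusted p = 0.0442). The retinoblastoma family genes Rb1 (5.45 ± 0.22 and 5.88 ± 0.26) and Rbl2 (6.39 ± 0.26 and 6.77 ± 0.12) had the smallest p-values, with a log2 change for Rb1 of -0.42, or -0.26 with the mean of its probe sets, followed by Ndn (2.76 ± 0.23 and 3.05 ± 0.21) and Txnip (9.33 ± 0.12 and 9.55 ± 0.16).

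Lists of stress and mitochondrial genes did not pass either. Targets of ATF4 and the integrated stress response were higher for 21 of 25 genes, with a median of 0.13 (camera adjusted p = 0.0722; 0.677 with an estimated correlation). Their mean level was 4.11 ± 0.09 in Elektra and 3.95 ± 0.07 in wild type (exact permutation p = 0.0571 unadjusted, 0.978 adjusted over the 28 lists). Vldlr was 4.09 ± 0.55 and 3.37 ± 0.54, and Nupr1 was 3.33 ± 0.21 and 3.07 ± 0.15. Gpt2 (0.34) and Aldh18a1 (0.32) had smaller log2 changes. Nuclear-encoded respiratory chain genes were higher for 29 of 34 (median 0.08, adjusted p = 0.0728). Cox6c (7.31 ± 0.11 and 7.12 ± 0.11; log2 change 0.19, or 0.0984 with the mean of its probe sets) had the smallest p, with Ndufb5 (0.17) and Uqcrq (0.19) the same way in log2 change and Ndufs3 (-0.15) the other. All 13 mitochondrially encoded genes were lower (median -0.08, adjusted p = 0.0722), among them ND6 (5.06 ± 0.48 and 5.50 ± 0.13), ND5 (-0.21), ND4 (-0.12) and the cytochrome oxidase gene COX2 (-0.12). With a term for arrays numbered 1 and 2 against 3 and 4 in the fit, the G2/M (adjusted p = 0.0326), ATF4 (0.0309), respiratory chain (0.0309) and mitochondrially encoded (0.0309) lists passed. None of them did so in that fit with the correlation estimated (adjusted p = 0.976, 0.700, 0.913 and 0.913, in this order). With quantile normalization the respiratory chain (median 0.14, camera adjusted p = 0.000599), ATF4 (0.17, 0.0151) and mitochondrially encoded (-0.07, 0.0455) lists passed. On leaving out each array, the respiratory chain median lay between 0.0418 (without Elektra replicate 3) and 0.14 (without Elektra replicate 2), and the mitochondrially encoded median between -0.17 (without wild type replicate 2) and -0.0521 (without wild type replicate 4). None of the 28 lists passed with the correlation estimated.

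Lymphoid priming genes were divided. Satb1, a chromatin organiser of lymphoid progenitors, was 4.05 ± 0.22 in Elektra and 4.64 ± 0.21 in wild type, and was the only one of 20 to pass adjusted over the list alone (adjusted p = 0.0348; 0.885 over all genes). Irf4 was dim at 1.77 ± 0.14 and 1.55 ± 0.14, opposite in direction to Satb1 and Flt3. The list as a whole did not pass (14 of 20 lower, median -0.05, adjusted p = 0.498). Among 37 interferon-stimulated genes, Rsad2 passed adjusted over the list alone (adjusted p = 0.0219). No gene of any other list passed this way. Such an adjustment makes no allowance for the 31 lists looked at, so chance may account for the passes of Satb1 and Rsad2. Iigp1, a GTPase gene of intracellular defence, was 6.21 ± 0.18 in Elektra and 5.78 ± 0.17 in wild type, Oas3 was 4.16 ± 0.28 and 3.91 ± 0.12, and Ifi203 was 4.72 ± 0.06 and 4.96 ± 0.18. Of the 37 genes 22 were higher (median 0.08, adjusted p = 0.403). The list passed with quantile normalization (median 0.15, adjusted p = 0.0151), with array weights (0.0208), without Elektra replicate 2 (0.00531), without wild type replicate 4 (0.0272) and without the 3 arrays that stand apart (median 0.23, 3.31e-06), and in none of the other alternatives run. The last of these fits set 2 Elektra arrays against 3 wild-type ones. With the inter-gene correlation estimated over all arrays (0.259), the camera adjusted p of the list was 0.980. On leaving out each array the median lay between 0.00755 (without wild type replicate 2) and 0.12 (without Elektra replicate 2).

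**Figure D2:**
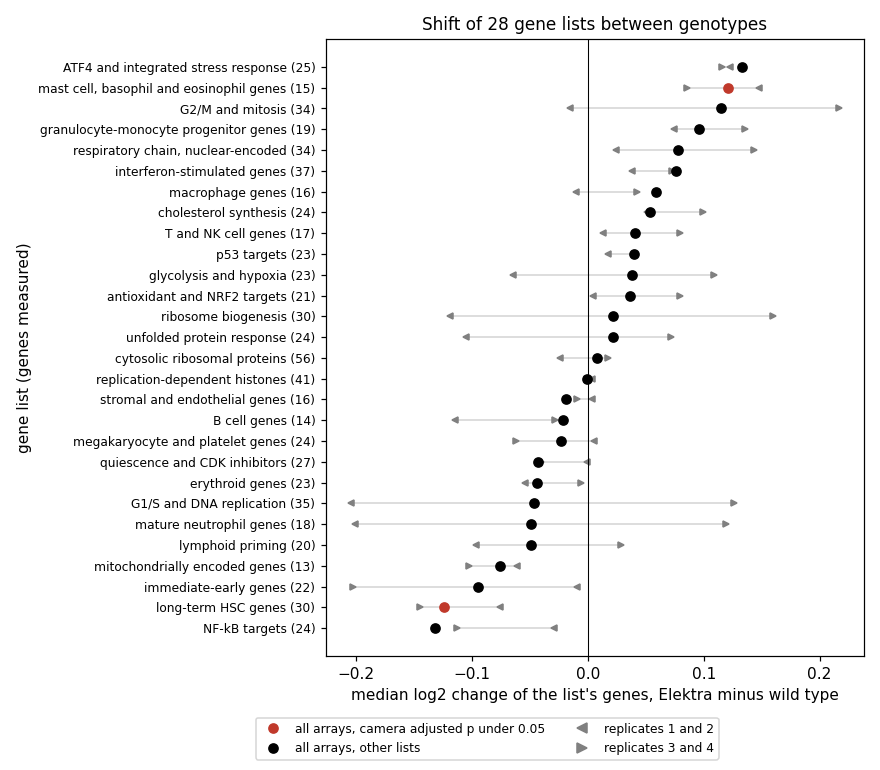
Median log2 change of each of the 28 gene lists (horizontal axis), Elektra minus wild type, over all arrays (circles) and within arrays numbered 1 and 2 or 3 and 4 (grey triangles). Red circles mark the lists past the threshold, long-term HSC genes (-0.12) and mast cell, basophil and eosinophil genes (0.12), and many of the other lists lie on both sides of 0.

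Markers of other marrow cells gave no list past the threshold beyond that of mast cells. Granulocyte-monocyte progenitor genes were higher for 14 of 19 (median 0.10, adjusted p = 0.179). Mature neutrophil genes had a median of -0.05 (adjusted p = 0.883), macrophage genes 0.06 (0.883), erythroid genes -0.04 (0.948), and megakaryocyte and platelet genes -0.02 (0.403). B cell genes, at a mean level of 1.86 ± 0.03 in Elektra and 1.90 ± 0.05 in wild type, had a median of -0.02 (adjusted p = 0.429). The medians were 0.04 for T and NK cell genes (0.617) and -0.02 for stromal and endothelial genes (0.948). Among the pathway lists, the median log2 change was -0.13 for NF-kB targets (0.403), 0.02 for the unfolded protein response (0.948), 0.05 for cholesterol synthesis (0.948) and 0.01 for cytosolic ribosomal proteins (0.948). It was 0.02 for ribosome biogenesis (0.948), 0.04 for p53 targets (0.948), 0.04 for glycolysis and hypoxia (0.948), 0.04 for antioxidant and NRF2 targets (0.948) and 0.00 for replication-dependent histones (0.948), each with its camera adjusted p. The median and the test pointed in different directions for the unfolded protein response and the histones, and the median and the mean differed in sign for erythroid genes, cytosolic ribosomal proteins and histones.

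Some genes differed far more between arrays of the same genotype than between genotypes. Immediate-early genes, the fast transcriptional response to stimulation and stress, were much higher in the arrays numbered 1 and 2 of both genotypes. Fos was at least 7.64 in those 4 arrays and at most 6.71 in the other 4, Egr1 at least 6.09 against at most 4.76, and Klf6 at least 7.56 against at most 5.88. The heat-shock gene Hspa1a was at least 7.24 against at most 2.72. Between genotypes the immediate-early list did not pass (8 of 22 higher, median -0.09, adjusted p = 0.837). Without Elektra replicate 1 it did (median -0.39, adjusted p = 0.0291), and without wild type replicate 2 the median turned to 0.13 (adjusted p = 0.720). Both fits hold unequal numbers of arrays 1 and 2 from the 2 genotypes, so their medians mix this split with genotype. Egr2 was 2.51 ± 0.09 in Elektra and 2.26 ± 0.10 in wild type, while Fosb (7.80 ± 1.73 and 8.57 ± 0.84), Atf3 (3.57 ± 1.47 and 2.94 ± 0.68) and Ier2 (5.02 ± 0.75 and 5.39 ± 0.70) varied widely within each genotype. Elektra replicate 3 and wild type replicate 4 alone had a strong signal from a few immunoglobulin genes, such as an Igkv14 gene (9.58 and 8.56). Elektra replicate 2 alone had a strong signal from a set of predicted genes led by Gm10800 (10.2). These genes, including Fos, Egr1, Klf6 and Hspa1a, were singled out after their values were seen.

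**Figure D3:**
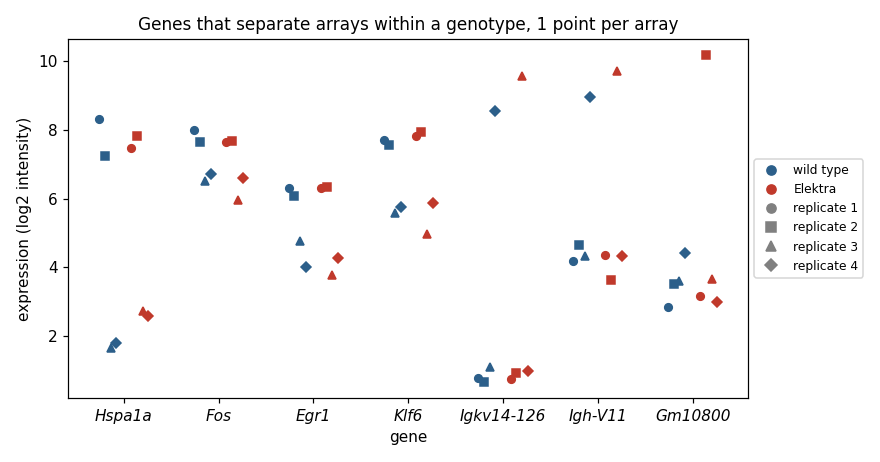
Log2 intensity (vertical axis) of 7 genes in each array, chosen after their values were seen, by genotype (colour) and replicate number (symbol). Hspa1a, Fos, Egr1 and Klf6 separate replicates 1 and 2 from 3 and 4 in both genotypes, an Igkv14 gene and Igh-V11 are high in Elektra replicate 3 and wild type replicate 4, and Gm10800 is high in Elektra replicate 2.

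In the authors' deposited table, 1741 probe sets, or 5.06%, had a p-value under 0.05, and 0 remained after Benjamini-Hochberg adjustment computed here. The authors' deposited table gave 52 probe sets a fold change of 2 or more in either direction, of which 19 had a p-value under 0.05.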

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

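The tests of receptor genes and of genotype were chosen only after the values were seen; those of plasma cell and B cell genes were chosen before. Within each genotype, 19 of 246 groups of 4 arrays had 1 array far from the other 3, where chance flags about 1 in 20 groups. The immunoglobulin and predicted genes described next, singled out because of their values, account for 12 of the 19. With members of all 28 lists counted, the number was 33 of 378 groups against 18.9 by chance. The same singled-out genes and their 12 flags are within the 33, so this count is no separate support for an excess.

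In Elektra replicate 3 and wild type replicate 4, an Igkv14 gene measured 9.58 and 8.56 against means of 0.87 and 0.83 in the other 3 arrays of each genotype, Igh-V11 9.72 and 8.95 against 4.10 and 4.39, and Ighv11-1 8.49 and 7.75 against 3.61 and 3.33, while Igkv6-23 measured 8.42 in wild type replicate 4 against 2.05 and 9.24 in Elektra replicate 3. The Elektra genotype is argued against, since 3 Elektra arrays lack the signal and 1 wild-type array has it. B cells as a sizeable share of the sorted cells are argued against as well. The 13 B cell genes other than immunoglobulin had a median excess of -0.0416 in the 2 arrays, 6 of them higher, with Cd79b at -0.19, Blnk at 0.03 and Bank1 at 0.32. The B cell list was dim, at mean levels of 1.86 in Elektra and 1.90 in wild type, so this test could miss a small number of B cells. Ighm, an immunoglobulin gene and so not part of the test, had an excess of 1.57. Plasma cells, which the sort gate is meant to exclude, may still account for the signal, because 15 of their genes had a median excess of 0.0124 but went both ways (8 higher, upper quartile 0.201; Sec11c -0.01, Edem1 -0.04, Ell2 -0.35, Creld2 0.55). That median met the bound of 0.1 set beforehand for excluding them, and the decision to ask that the upper quartile stay under it too was made after the values were seen.

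In Elektra replicate 2, Gm10800 measured 10.2 against a mean of 3.27 in the other 3 Elektra arrays, Gm10719 7.01 against 1.30, Gm10718 6.74 against 1.09, Gm10717 4.94 against 1.07 and Gm11168 5.61 against 0.80. These predicted genes are known to hold satellite repeats, which was not checked here against a genome. The Elektra genotype alone is argued against only by the absence of the signal from the other 3 Elektra arrays (median of the 5 genes -0.34 relative to the highest wild-type array), which is also how the genes were singled out. Genomic DNA carried into the sample may be the source and stays open: 28.6% of 1459 olfactory and vomeronasal receptor genes had their highest value of the 8 arrays there, against at most 15.1% in any other array. A higher floor in an array of lower weight (0.419) would raise the same genes and was not told apart.

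The other groups with 1 array far from the rest are given as values. Among wild-type arrays, Elac1 was 3.55 in replicate 2 against a mean of 3.38 in the other 3, Aurka 2.89 in replicate 3 against 2.66, Nuf2 1.81 in replicate 1 against 3.00, Mcpt4 0.88 in replicate 1 against 0.75, and Ifi203 4.70 in replicate 2 against 5.05. Among Elektra arrays, Ccne1 was 4.14 in replicate 4 against 3.45. The mean of the glycolysis and hypoxia list was 4.71 in Elektra replicate 2 against 5.02.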

How the results depend on the processing

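The batch term, the pooled-variance test and the fits without 2 or 3 arrays that stand apart were chosen only after the data were seen. The count of genes past an adjusted p of 0.05 was 0 under each of the 23 alternatives that gave one. The limma count at an unadjusted p under 0.05 lay between 1408 and 2119 over the fits of 30918 genes, was 1062 of 18551 with dim probe sets left out, and was 1560 in the pooled-variance test. Of the 77 genes named besides Slfn2, 9 changed sign somewhere: Slfn1, Slfn3, Slfn4, Slfn5, Slfn8, Slfn9, Slfn10-ps, Cd34 and Gpt2. Of the 1690 genes at an unadjusted p under 0.05, 800 were higher in Elektra. With quantile normalization 1209 of 1826 were higher, and with dim probe sets left out 409 of 1062. The mast cell list has no value with dim probe sets left out, since too few members stay. Dim genes limit what these arrays show: the median level of all genes was 2.02. Where a result moved, the cause was not tested.

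The number of lists past the threshold, 2, became 5 with quantile normalization, 4 with dim probe sets left out, 6 with array weights, 6 with the batch term, 6 at an adjusted p of 0.10, 6 with camera on ranks, and 0 with camera at an estimated correlation or with fry. It was 1 without the 2 immunoglobulin arrays, 4 without the 3 arrays that stand apart, and between 1 (without wild type replicate 1) and 7 (without Elektra replicate 1) on leaving out each array. Long-term HSC genes passed under 15 of 22 alternatives. Their median was -0.0582 with quantile normalization, -0.0719 without the 2 immunoglobulin arrays and 0.00872 without the 3 arrays, none of these past the threshold. With the estimated correlation or fry it was -0.12 and not past it, and on leaving out each array it lay between -0.16 and -0.0416. Mast cell genes passed under 11 of 21, with 0.12 for quantile normalization, without the 2 arrays, with the estimated correlation and with fry, 0.0675 without the 3 arrays, and 0.0973 to 0.15 on leaving out each array. Of 22 alternatives, G2/M genes passed under 13, respiratory chain genes under 10, ATF4 genes under 9, mitochondrially encoded genes under 7, interferon-stimulated genes under 5, and NF-kB and granulocyte-monocyte progenitor genes under 1 each. G1/S and quiescence genes passed under 2 each, and immediate-early and ribosome biogenesis genes under 1 each. For the first 7 of these lists, the medians on leaving out each array lay between 0.0124 and 0.16, 0.0418 and 0.14, 0.0945 and 0.14, -0.17 and -0.0521, 0.00755 and 0.12, -0.17 and -0.0161, and 0.0687 and 0.14, in this order.

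With the replicate number as a block, 0 genes passed and the count of lists became 6. Arrays with the same number deviated from their genotype's mean with correlations of 0.195, 0.0403, 0.160 and 0.0724, so the numbers were not taken to pair the samples, and not every sample correlated best with its own number.

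Signs turned as follows. Quantile normalization: G1/S 0.0349, quiescence 0.0469, lymphoid priming 0.00227, neutrophil 0.00784, erythroid 0.0172, histones 0.00835. Dim probe sets left out: histones 0.0104. Array weights: Slfn1 -0.00841, G1/S 0.0647, stromal 0.00376, ribosomal proteins -0.00118. Without the 2 immunoglobulin arrays: Slfn3 0.0905, Slfn4 -0.0180, Slfn5 0.0110, Slfn8 -0.0883, unfolded protein response -0.0438, cholesterol -0.0138, ribosome biogenesis -0.0713, glycolysis -0.0479, histones 0.0454. Without the 3 arrays that stand apart: Slfn1 -0.12, Slfn3 0.33, Slfn4 -0.0159, Slfn5 0.0178, Gpt2 -0.00739, long-term HSC 0.00872, G1/S 0.11, neutrophil 0.0685, megakaryocyte 0.0101, stromal 0.00769, cholesterol -0.0874, histones 0.0314. On leaving out each array, the lowest and highest values were -0.12 and 0.13 for Slfn2, -0.0700 and 0.15 for Slfn1, -0.23 and 0.0543 for Slfn3, -0.20 and 0.14 for Slfn5, -0.26 and 0.29 for Slfn8, -0.29 and 0.0185 for Slfn9, -0.21 and 0.00820 for Slfn10-ps, -0.10 and 0.0237 for Cd34. For lists they were -0.14 and 0.13 for G1/S, -0.16 and 0.0481 for quiescence, -0.16 and 0.12 for neutrophil, -0.00343 and 0.0834 for macrophage, -0.12 and 0.0160 for erythroid, -0.0835 and 0.0361 for megakaryocyte, -0.0607 and 0.00746 for B cell, -0.0336 and 0.0234 for stromal, -0.39 and 0.13 for immediate-early, -0.0501 and 0.0524 for unfolded protein response, -0.0578 and 0.15 for cholesterol, -0.0607 and 0.11 for ribosome biogenesis, -0.0416 and 0.0848 for p53, -0.0392 and 0.13 for glycolysis, -0.0462 and 0.0592 for histones.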

Other observations

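The tests of immediate-early genes, of Hspa1a between genotypes, of the splits at an adjusted p, of the balanced splits and of a quiescence index were chosen only after the values were seen; those of the other heat-shock genes and of the other splits were chosen before.

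Arrays numbered 1 and 2 differed from those numbered 3 and 4 in both genotypes, among other genes in immediate-early genes and in the heat-shock genes Hspa1a and Hspa1b. In limma 26 genes passed an adjusted p of 0.05 in this comparison, 25 of them higher in 1 and 2, and 8 belonged to the immediate-early list. This grouping of the arrays was itself chosen after the data were seen, so its p-values are no independent support for it. Hspa1a, Fos, Egr1 and Klf6, singled out after their values were seen, are among the 26. Hspa1a differed by 5.53, Hspa1b by 4.33 and the predicted gene Gm26802 by 3.98. Among the others were the antiproliferative gene Btg2 (2.25), the transcription factor genes Klf6 (2.22), Klf4 (2.21), Nr4a1 (2.19) and Egr1 (2.06), and the chaperone gene Hspa5 (1.37). Of the 28 lists 16 passed in camera, G1/S and DNA replication genes (median -0.44, adjusted p = 2.55e-11) next after immediate-early genes. The G1/S median was -0.55 in Elektra and -0.14 in wild type, and its camera adjusted p was 0.269 with an estimated correlation. With an estimated correlation 2 lists passed, immediate-early genes (median 1.25, adjusted p = 0.0124) and quiescence genes and CDK inhibitors (median 0.10, adjusted p = 0.0419).

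The Elektra genotype alone is argued against as the origin of this split by its presence in wild-type arrays, where Hspa1a differed by 6.07, against 4.99 in Elektra. The comparison of Hspa1a between genotypes (0.40, exact permutation p = 0.629) adds nothing, since the gene was chosen for the split. Stress of cell handling shared by arrays 1 and 2 may be the cause but stays open: the immediate-early genes, with medians of 1.33 in Elektra (21 of 22 higher) and 1.10 in wild type (19 of 22), are part of the split itself. A handling batch, which the labels do not give, stays open too, as the other 18 heat-shock genes had medians of -0.0338 in Elektra (9 higher) and 0.24 in wild type (13 higher). The Elektra value met the bound of 0.1 set beforehand for excluding it, but the genes went both ways, and the decision that such a median settles little was made after the values were seen.

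The share that chance can give was examined with all 35 splits into 4 and 4. Chance cannot be excluded for the 2 lists past the threshold, since 33 of the 35 splits gave as many and the highest other gave 16. It cannot be excluded for the 1690 genes at an unadjusted p under 0.05 (6 splits gave as many, highest other 2272). With 0 genes in limma at an adjusted p, all 35 splits give as many whatever the data (highest other 26), so that comparison says nothing about chance. The highest other value was in each case that of arrays 1 and 2 against 3 and 4, which points to a structure of the samples. Of the 35 splits 18 have 2 of the arrays numbered 1 and 2 on each side, as the real one does, too few for a share under 0.05. Among these the real split gave 1690 genes at an unadjusted p and the highest other 1479, and 16 of the 18 gave as many lists, the highest other 9.

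A hypothesis is that Elektra progenitors may be less quiescent, with G2/M genes higher and long-term HSC genes lower. The mean of the G2/M list minus that of the HSC list was -1.16 ± 0.22 in Elektra and -1.39 ± 0.23 in wild type, a difference of 0.23 (exact permutation p = 0.229). It was 0.13 between arrays 1 and 2 and 0.33 between arrays 3 and 4, so the test did not exclude the hypothesis. It could not bear the hypothesis out either, since both lists were picked for having moved this way. The G2/M median alone was -0.02 between arrays 1 and 2. Of 27 quiescence genes and CDK inhibitors 16 were lower (camera adjusted p = 0.256), and of 35 G1/S genes 21 were lower.

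The 6955 probe sets outside the annotated table had a mean level of 2.90 ± 0.09 in Elektra and 3.05 ± 0.09 in wild type (exact permutation p = 0.0857). Among genes singled out after their values were seen, Snora69 had a log2 change of -1.89 and Rpl5 of -1.15, both with a limma adjusted p of 0.885.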
